A study of Mus musculus with 24 samples.

How the data were processed

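The series measured liver RNA of wild-type, Cyp1b1-null and R-Cyp1b1-null mice at birth (PN0) and weaning (PN21) after a vitamin A sufficient or deficient maternal diet, on 24 arrays in 10 groups. Per the file headers, the authors scanned each array in 1 colour and extracted it with Agilent Feature Extraction 10.7.3.1, which gives a background-subtracted spot intensity, a mean and a local background intensity, and marks for outliers and for signal well above background. Per the submitters' processing notes, Agilent Feature Extraction and limma were used, and no versions are stated there. The authors' processed values in the deposited series table are the same linear intensity: they equal the scanner files' processed signal within a relative difference of 0.00497. The arrays' probe design refers to mouse build mm9 per the file headers, so no coordinates are printed. Each array held 45018 spots, of which 43379 were not controls, for 41174 distinct probes. The arrays lay on 6 slides of 4 arrays and were scanned on 3 days. Slides 1 to 3 each held 1 array of every wild-type and R-Cyp1b1-null PN21 group, the 4 null PN21 arrays shared a slide, and wild-type and null PN0 arrays each had their own.

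From these files, log2 of the processed signal minus the 75th percentile of each array was computed, after control spots and 2048 outlier spots were left out and spots of a probe were averaged. Probes were named through RefSeq accessions (28223), current symbols (5394) or unique synonyms (351) of the GRCm38.p6 gene table, and 7206 kept the name in the file. A probe was measured if it was well above background on every array of at least 1 group (30927 probes), and the brightest probe stood for each gene (20452 genes). The 3 wild-type sufficient PN21 arrays came from 1 pool, per the labels, and were averaged into 1 sample, so 22 samples entered the fit. Group means were fitted to all groups together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), with 12 residual and 3.98 prior degrees of freedom. The 9 comparisons of the design and 7 tests of differences between effects were drawn from that fit, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. P-values measure the spread between arrays within groups, estimated over all groups together. That spread takes in differences between pools and litters, which are few. It also takes in differences between slides where the arrays of a group lay on several, and arrays that correlate poorly with the rest. A gene with no probe well above background on any array of a group has only a bound there: the fold "at least" is the mean of the brighter group over the mean of, per array, the higher of the lowest signal well above background and the probe's own.

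Gene lists (33 pathways and cell types) were tested with camera, preset correlation 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Of 297 such tests 138 were called, and 8 with an estimated correlation; 323 missing gene values were filled with the group mean. Members were counted over all genes and adjusted over the list alone. Before the data were examined, the comparisons, the lists, the alternatives and the rule for named genes were fixed. The rule took 10 genes of the study question, the 6 largest rises and 6 largest falls called with a gene symbol or else the 5 smallest p-values, up to 3 called members per list, and up to 4 genes per test of a difference. Other list members given as examples (Sqle, Cyp51, Lss, Elovl6, Camp, Mpo, S100a8, Cel, Mb, Mmp13, and Eln, Igf2, Afp and Hamp2 outside their calls) were chosen after their values were seen. Some genes that the rule took are not reported here. Simulated groups against the shared control gave the correlations of unchanged groups, from 100 draws. The PN21 control is 1 pool; the PN0 control was split into its 2 arrays, 1 for each effect, after the result was seen.

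The method was tested on simulated data with 50 genes changed per size among 20452. In simulated null against wild type at PN0 it recovered 16% of genes changed by 2 (log2), 74% changed by 4 and 94% changed by 6. In simulated wild-type diets at PN21 these shares were 6%, 64% and 94%, and in simulated R-Cyp1b1-null diets 20%, 92% and 98%. Of genes changed by 1 it recovered 0%, 2% and 0% in the same order, so changes of that size would be missed. Calls among unchanged genes numbered 3, 5 and 8. The simulated noise was independent, with 1 spread per gene on all arrays. Arrays that correlate poorly with the rest and differences between slides were thus not simulated.

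Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, no filter on dim probes, the mean of probes, the authors' series table, groups of the same age in the fit, the slide as a block or random block, the replicate number as a block, the 3 arrays of the shared pool as replicates (the block fits count them so too), and leaving out each array. Chosen after seeing the data were fits without the 2 arrays whose median correlation was under 0.9, with and without the slide block or quantile normalization, array weights, and the control array scanned on the day of the PN0 arrays.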

Results

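Liver RNA of mice was measured on 24 arrays of 1 colour (Cy3), in 10 groups defined by age, genotype and the diet of the dam. From embryonic day 4.5 the dams received a defined diet with vitamin A (sufficient) or without it (deficient), and offspring livers were taken at birth (PN0) or at weaning (PN21). Birth samples were pools of a litter, and weaning samples were males, with the RNA of 1 to 4 mice on an array. The genotypes were wild-type C57Bl/6J, Cyp1b1-null, and R-Cyp1b1-null, a line of the null mice that resists diet-induced obesity. Cyp1b1 encodes a cytochrome P450 that oxidises oestradiol, retinoids and xenobiotics. The wild-type PN21 groups and both R-Cyp1b1-null groups held 3 arrays each, and the other 6 groups held 2 arrays each. The 3 arrays of wild-type sufficient PN21 carried the same pool of 4 mice and were counted as 1 sample. The 75th percentile of the signal lay between 155.6 and 1963 across arrays, and 33.7% to 90.2% of probes were well above background. The number of arrays limits the precision. The median correlation with the other arrays of the same age was 0.496 for R-Cyp1b1-null sufficient array 3 and 0.786 for wild-type deficient PN21 array 3, and 0.903 to 0.97 for the other arrays. Values are log2 signals relative to the 75th percentile of each array, differences are log2, and adjusted p-values come from limma. A fold written as "at least" sets the brighter group against the detection limit of the dimmer one. It holds for the main fit, and several such genes differed by less under other settings. Where a probe was well above background on only part of the arrays of a group, the difference takes in signal near background.

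The Cyp1b1 probe with the higher signal separated the genotypes. Its value was at or above -0.96 on every Cyp1b1-null and R-Cyp1b1-null array and at or below -1.29 on every wild-type array. At PN0 on the sufficient diet it averaged 0.54 ± 0.55 (SD, n = 2) in null liver and -4.74 ± 0.47 (n = 2) in wild type, at least 16-fold higher (adjusted p = 0.00624). At PN21 the null group lay 2.95 ± 0.92 (SE) above wild type (adjusted p = 0.107) and the R-Cyp1b1-null group 2.22 ± 0.87 above it (adjusted p = 0.818). The part of the gene that was deleted is not given in the sources used here, so this probe checks nothing about the deletion. A second Cyp1b1 probe did not separate the lines, and with the mean of the probes the null differences were 3.08 at PN0 and 0.34 at PN21. The PN0 call ended without wild-type sufficient array 1 or without null sufficient array 2, where the difference was 4.95 and 4.89.

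**Figure D1:**
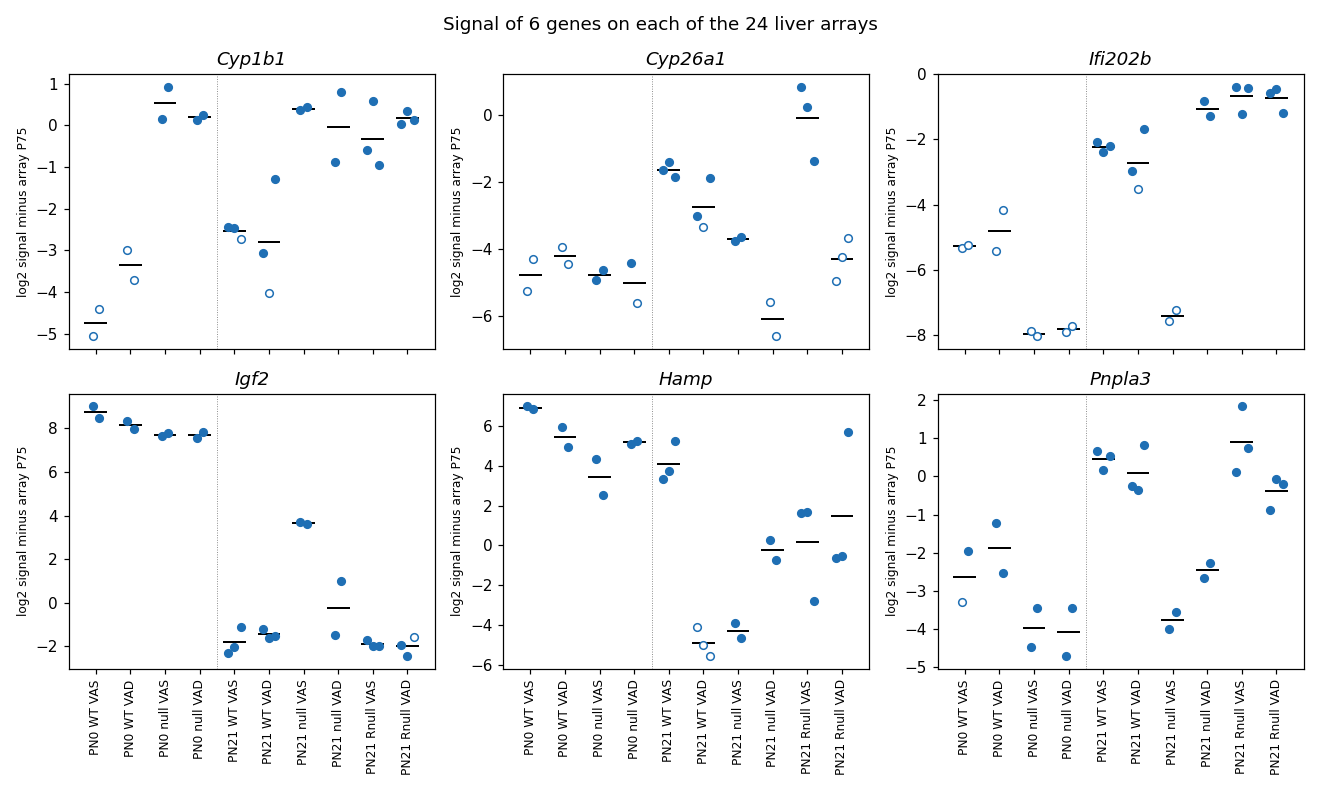
Signal of Cyp1b1, Cyp26a1, Ifi202b, Igf2, Hamp and Pnpla3 on each of the 24 arrays, as log2 relative to the 75th percentile of the array (y axis), by group (x axis). Each point is an array, open where the probe was not well above background, and each bar is the group mean. Cyp26a1 averages -4.30 in the deficient and -0.10 in the sufficient R-Cyp1b1-null group.

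The first comparison asked what maternal vitamin A deficiency changes in wild-type liver at birth. The genes with the smallest p-values were higher in the deficient litters. Runx2, a transcription factor of bone formation, was at least 2.04-fold higher, on both deficient arrays well above background (n = 2 and 2, limma adjusted p = 1), and with the mean of its probes 1.88 higher. The next were Gm16508 (at least 8.08-fold), Yju2 (at least 1.4-fold), Olfr502 (at least 1.51-fold) and Lvrn (at least 1.73-fold). Of 31 extracellular matrix genes, 24 lay higher, with a median of 0.58 (camera adjusted p = 0.00801), among them Eln, which encodes elastin (1.98 ± 0.65), and the collagenase gene Mmp13 (2.03 ± 0.68). All 35 genes of oxidative phosphorylation lay lower, with a median of -0.41 (adjusted p = 0.00033). With an estimated correlation the adjusted p was 0.879 for both lists. Without wild-type sufficient array 1 the medians were 0.46 and -0.05 (adjusted p = 0.101 and 0.118), without deficient array 2 the extracellular matrix median was 0.56 (adjusted p = 0.145), and without sufficient array 2 the oxidative phosphorylation median was -0.73. No member of either list passed limma's test, over all genes or adjusted over the list alone. Xist measured -5.29 and 2.54 on the deficient arrays and 2.54 and 4.01 on the sufficient ones. The sex of the pooled pups thus stays open as a cause in this comparison. Limma called 0 of 20452 genes, with 941 at an unadjusted p under 0.05. Without the 2 arrays of low correlation, which belong to other groups but widen the shared spread, 569 genes were called, 556 of them higher, Runx2 included (adjusted p = 0.00314), and with quantile normalization as well 170 were called, 110 higher and 60 lower.

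The second asked what the null genotype changes at birth on the sufficient diet. Null liver showed 154 genes higher and 347 lower than wild type. Extracellular matrix genes were among those that rose: Eln at least 5.45-fold and Loxl1, an enzyme of elastin crosslinking, by 2.42 ± 0.58 (n = 2 and 2, adjusted p = 0.041 for both). The brightest probe of Acta2, a smooth muscle actin gene, also passed (3.49 ± 0.76, adjusted p = 0.0336), but Acta2 was not called with the mean of its probes (0.83) or without null sufficient array 2 (2.50). Also called higher were Fitm1 (at least 8.48-fold), Cenpb (at least 21.2-fold) and the apoptosis gene Bax (at least 17.8-fold). Across the alternative settings they differed by 2.32 to 6.94, 2.69 to 5.51 and 2.29 to 4.99 (log2), in part under these bounds. The brightest probes of Ppp5c and Hira were called too, but were not well above background in wild type, so no size is given for them; with the mean of the probes the 2 genes differed by 2.48 and 1.90. Without null sufficient array 2 Fitm1 differed by 3.17 and was not called. The Y-linked genes Kdm5d (at least 11.4-fold), Eif2s3y and Ddx3y (adjusted p = 0.0202 and 0.0101, each well above background on 1 of the 2 null arrays) fell, together with Syt10 (-7.97), Flg (at least 30.8-fold) and Orm3, an acute phase gene (at least 9.51-fold). The brightest probe of the progranulin gene Grn was also called lower (-7.63), but it measured 2.61, 2.82 and 8.18 on the 3 arrays of 1 wild-type PN21 pool. A second Grn probe measured 3.81 and 3.60 in wild type and 4.07 and 3.69 in null liver, and with the mean of the probes Grn differed by -3.73. Kdm5d had the smallest p, 1.17e-05 after adjustment. Across the alternative settings Kdm5d ranged from -5.38 to -0.59, Flg from -8.29 to -1.71 and Orm3 from -4.85 to -0.63. The bounds given for these genes thus hold for the main fit only. Skeletal muscle markers lay higher, with a median of 3.06 over 17 genes (camera adjusted p = 4.93e-09, with 2 that rose adjusted over the list alone), and so did 17 of 20 exocrine pancreas markers (median 1.89, adjusted p = 5.51e-07). The extracellular matrix list had a median of 0.40 (adjusted p = 0.000195), and 2 of its 31 members rose over all genes, or 3 rose and 1 fell adjusted over the list alone. With an estimated correlation the adjusted p was 0.96 for all 3 lists. The muscle and pancreas markers stood high on 1 of the null sufficient arrays: without array 2 their medians were -0.32 and -0.38 (adjusted p = 0.593 and 0.847) and that of the extracellular matrix list was 0.20 (adjusted p = 0.0892). Without null sufficient array 1 the muscle and pancreas medians were 6.66 and 4.17, and without wild-type sufficient array 1 the muscle and extracellular matrix medians were 1.89 and 0.22.

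The wild-type PN0 arrays of both diets lay on 1 slide and the null PN0 arrays of both diets on another, so batch and group cannot be told apart in this comparison. Wild-type PN0 arrays held values near the detection limit for several genes that rose. Bax averaged -4.08 there, against -1.03 in wild-type PN21 and 0.70 in null PN0 liver. The median of all genes was -0.483, so the falls above are in part relative to a shift of the whole profile. With quantile normalization that median was -0.182, and the fit called 127 genes higher and 19 lower and 43 of these were among the 501. Leaving out a single array left between 1 call (without wild-type sufficient array 1) and 47 calls (without null sufficient array 1), with 15 and 3 for the other 2 arrays. Of 131 genes within 20 Mb of Cyp1b1 0 were called, against 315 of 16708 elsewhere (two-sided Fisher's exact test, p = 0.183). At the share of 1.89% called elsewhere, few calls would be due among so few genes. The test thus says little about changes near Cyp1b1.

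Between the diets in null liver at birth, the pancreas genes Ctrc (-3.68 ± 1.08) and Cel (-2.19 ± 0.80) and the muscle gene Mb (-4.04 ± 1.80) lay lower in deficient litters. Exocrine pancreas markers had a median of -2.19 over 20 genes (camera adjusted p = 1.83e-33, and adjusted p = 0.0481 with an estimated correlation), and skeletal muscle markers one of -3.19 over 17 genes (adjusted p = 1.22e-32, and adjusted p = 0.071 with an estimated correlation). Both rested on null sufficient array 2, where Ctrc measured 3.57 against -1.80 on array 1. Without that array Ctrc, Cel and Mb differed by -0.99, -0.37 and -0.15, and without array 1 by -6.36, -4.02 and -7.92. Without deficient array 1 or 2 Mb differed by -1.61 and -6.46. Without sufficient array 2 the list medians were 0.09 and 0.49, and without array 1 they were -4.64 and -7.15. Without deficient array 1 the muscle median was -0.69, without deficient array 2 it was -5.72, and the adjusted p of the pancreas list with an estimated correlation was 0.156 and 0.0847, while that of the muscle list was 0.0327 without deficient array 2. Among the genes with the smallest p-values, Col8a1, a collagen of vessel walls, measured -2.10 ± 0.66 and Ldb3 -1.41 ± 0.47, and without null sufficient array 2 they measured -1.16 and -0.58. Without deficient array 1 Col8a1 measured -1.36, and without sufficient array 1 Ldb3 measured -2.23. Limma called 0 genes in this comparison, with 68 at an unadjusted p under 0.05 (n = 2 and 2). Leaving out null sufficient array 1 gave 11 calls, and leaving out null deficient array 1 gave 1 call.

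At weaning, wild-type offspring of deficient dams were compared with the wild-type control. Hamp, which encodes the iron hormone hepcidin, was well above background in the control pool at 4.09 and on no deficient array, where it averaged -4.88 ± 0.73 (SD, n = 3), at least 200-fold lower. Its difference of -8.97 ± 1.93 (SE), set against background, did not pass the test over all genes (limma adjusted p = 0.887, and 0.0552 with the slide as a block, a fit that counts the 3 arrays of the control pool as 3 samples). Within the 3 slides that held both groups it ranged from -10.78 to -7.43. Its paralog Hamp2 differed by -6.08 ± 1.69, and both passed adjusted over the list alone among 30 iron genes. The probe named for the renin gene Ren2 was on no deficient array well above background (at least 11.4-fold). It and Ppp1r3g, a regulator of glycogen synthesis (-3.87 ± 0.91), were lower on 3 of 3 slides. So was the brightest probe of Ren1 (-3.20 ± 0.80), but a second Ren1 probe was higher on each slide (-1.02, -1.86 and 0.48 against -1.27, -2.48 and -2.56), and with the mean of the probes Ren1 differed by -0.95. On the control arrays the Ren2 probe measured -0.6, -0.31 and 0.79 and the brightest Ren1 probe -0.69, -0.19 and 0.69. Whether these probes tell the 2 genes apart was not tested. The Ren2 probe was called with the slide as a block (adjusted p = 0.00826), again with the pool counted as 3 samples. The control is 1 pool, assumed to vary like the other groups.

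Of 35 lipogenic genes 33 lay lower in the deficient wild type, with a median of -1.14 (camera adjusted p = 6.26e-08), for example Elovl6 (-3.03 ± 1.32), Scd1 (-2.69 ± 1.88) and Fasn (-2.12 ± 1.63), enzymes that elongate, desaturate and build fatty acids. Cell cycle genes had a median of -1.02 (adjusted p = 2.29e-06) and neutrophil markers one of 0.95 (adjusted p = 0.000199). These were among 17 lists called, 10 of which kept the call and direction without the 2 arrays of low correlation. With an estimated correlation the adjusted p was 0.616 for each of the 17. Lymphocyte markers (median 0.63, adjusted p = 0.000548) had medians of 0.62, 0.82 and 0.35 on the 3 slides and exocrine pancreas markers (1.05, adjusted p = 0.0378) of 0.30, 0.87 and 2.30. Adult hepatocyte genes (-0.51, adjusted p = 0.00364) had medians of 0.21, 0.01 and -1.96, so their fall lay on slide 3. With the slide as a block the lipogenic median was again -1.14, and within slides it was -0.60, -0.62 and -2.05. The cell cycle median was -0.77, -0.67 and -2.00, and the neutrophil median 0.44, 0.76 and 1.99. Slide 3 carried the deficient array of low correlation; without it the lipogenic median was -0.77 (adjusted p = 8.38e-10). Limma called 0 genes here, with 191 at an unadjusted p under 0.05. With the 3 arrays of the control pool as replicates 4 genes were called, namely Hamp, Ren2, Ppp1r3g and AK048933.

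The null genotype was next compared with wild type at weaning on the sufficient diet. Igf2, a fetal growth factor, rose by 5.49 ± 0.72 in null liver (3.66 ± 0.09, SD, n = 2, against -1.83 in the control pool, adjusted p = 0.00908), and by 5.23 with the mean of its probes, where it was not called. The 3 genes that fell were well above background on neither null array. Chrna4, a nicotinic receptor subunit, fell at least 34.3-fold (adjusted p = 0.00908). Ifi202b, an interferon-inducible gene whose expression differs between mouse strains, fell at least 10-fold (adjusted p = 0.00908). The aminopeptidase gene Lvrn fell at least 5.49-fold (adjusted p = 0.0487). Across the alternative settings Chrna4 ranged from -7.33 to -1.96, Ifi202b from -5.34 to -0.76 and Lvrn from -4.7 to -0.14, in part under these bounds. Close to the threshold were Pnpla3, a lipid droplet protein gene induced by SREBP1c (-4.22 ± 0.85, adjusted p = 0.0535), Hamp (-8.36 ± 2.05, adjusted p = 0.0546) and Afp, the fetal albumin (4.23 ± 1.06, adjusted p = 0.0572). Cholesterol synthesis genes had a median of -1.93 over 26 genes, with 1 higher (camera adjusted p = 0.000794), and Sqle measured -5.21 ± 1.52. Lipogenic genes had a median of -1.32 (adjusted p = 0.0156), with Elovl6 at -4.87 ± 1.40, Fasn at -3.51 ± 1.73 and Scd1 at -3.51 ± 1.99. With an estimated correlation the adjusted p was 0.738 for both. Without control array 2 the lipogenic median was -1.30 (adjusted p = 0.0526). Fetal liver genes had a median of 0.74 over 22 genes (adjusted p = 0.000794, and adjusted p = 0.152 with an estimated correlation), of which 1 rose, or 2 rose and 1 fell adjusted over the list alone.

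In all, Igf2, Chrna4, Ifi202b and Lvrn were the 4 genes called in this comparison, with 2461 at an unadjusted p under 0.05. Across the alternative settings, called or not, Igf2 differed by 4.39 to 5.84. The median of all genes was -0.179, and 0.029 with quantile normalization. The null arrays lay on 1 slide and the control on 3 others; with the slide as a random block 1636 genes were called, 1619 of them lower, and with quantile normalization 0 (limma, 950 at an unadjusted p under 0.05). Without either null array no gene was called (limma, 2004 and 1806 at an unadjusted p under 0.05), without control array 3 the calls numbered 1038 and without control array 2 they numbered 510. Hamp, Pnpla3, Afp, Sqle and Elovl6 passed without the 2 arrays of low correlation, where 2665 genes were called and all 4 were kept.

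In the R-Cyp1b1-null line on the sufficient diet at weaning, no gene differed from wild type by limma's test, with 183 at an unadjusted p under 0.05. The smallest p-values belonged to AK048933 (at least 1.65-fold), AU041770 (2.29 ± 0.63), Susd4, a complement regulator (-1.64 ± 0.49), AK076620 (2.04 ± 0.63) and Dmbt1, a mucosal defence gene (-3.71 ± 1.16), each with an adjusted p of 0.818 (n = 3 against 1 pool). Hamp measured -3.91 ± 1.93 (-2.43 without R-Cyp1b1-null array 3) and Cyp26a1, the retinoic acid hydroxylase induced by retinoic acid, 1.54 ± 0.82. Erythroid markers had a median of 0.59 over 29 genes (camera adjusted p = 0.016), and adjusted p = 0.632 with an estimated correlation. Their median was 0.34, 0.53 and 0.80 within the 3 slides and 0.59 with the slide as a block (adjusted p = 0.0208, the pool counted as 3 samples). It was 0.91, 1.06 and 0.30 without R-Cyp1b1-null arrays 1, 2 and 3, 0.31 without control array 2, and 0.73 without control array 1, where the call ended (adjusted p = 0.0517). Of the 22 lists called here, erythroid markers were the 1 that kept its call and direction without the 2 arrays of low correlation. In that fit 13 turned, and 1 of these was called in the opposite direction. Lipogenic genes, for example, had a median of -4.06 on the slide of R-Cyp1b1-null array 3 and of 0.25 and 0.17 on the other slides.

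Between the diets of the null line at weaning, Ifi202b rose from -7.41 ± 0.22 (SD, n = 2) in the sufficient to -1.05 ± 0.33 (n = 2) in the deficient group, at least 22.6-fold (adjusted p = 0.00011). Genes of cholesterol synthesis, the targets of SREBP2, rose as a group: all 26 lay higher, with a median of 1.92 (camera adjusted p = 8.58e-67, and adjusted p = 0.0104 with an estimated correlation). Sqle (4.91 ± 1.24), Cyp51 (3.27 ± 0.81) and Lss (2.38 ± 0.62) rose adjusted over the list alone (adjusted p = 0.0122 for each), and none of the 26 passed over all genes. Sqle measured 2.83 and 2.89 on the deficient and -2.45 and -1.64 on the sufficient null arrays, and 2.85, 3.24 and 3.39 on the wild-type sufficient arrays. Cyp51 measured 1.24 and 1.27, -2.15 and -1.88, and 0.79, 1.08 and 1.29 in the same order. For these 2 genes the sufficient null arrays were thus the low ones, and the deficient null arrays lay near wild type. Neutrophil markers fell as a group, with a median of -1.21 and 23 of 24 lower (adjusted p = 8.86e-40, and adjusted p = 0.0101 with an estimated correlation). Camp (-2.33 ± 0.73), Mpo (-1.84 ± 0.59) and S100a8 (-2.05 ± 0.65) were among the 4 that fell adjusted over the list alone, and measured -1.51, -1.22 and -1.31 without sufficient array 1. Fetal liver genes fell as a group, with a median of -0.28 over 22 genes (adjusted p = 1.09e-06, and adjusted p = 0.0101 with an estimated correlation). Igf2 measured -3.90 ± 0.59 (adjusted p = 0.0563 over all genes), fell adjusted over the list alone (adjusted p = 0.000121), and differed by -5.14 without deficient array 2, where it was called, and by -2.66 without deficient array 1. Afp measured -1.98 ± 0.87. Hamp measured 4.05 ± 1.68, and Cyp26a1 was at least 3.32-fold lower, on no deficient array well above background (limma adjusted p = 1 for both). Ifi202b was the 1 gene called, with 79 at an unadjusted p under 0.05, and all 4 arrays shared a slide. With an estimated correlation the list calls depended on single arrays: the adjusted p for cholesterol synthesis was 0.0545, 0.0675 and 0.0691 without deficient array 1, deficient array 2 and sufficient array 1, and for neutrophil markers 0.0879 and 0.136 without deficient array 1 and sufficient array 1, where their median was -0.69 and -0.76. For fetal liver genes it was 0.0879 and 0.0691 without these 2 arrays. With normexp background correction Ifi202b differed by 1.47 and was not called.

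**Figure D2:**
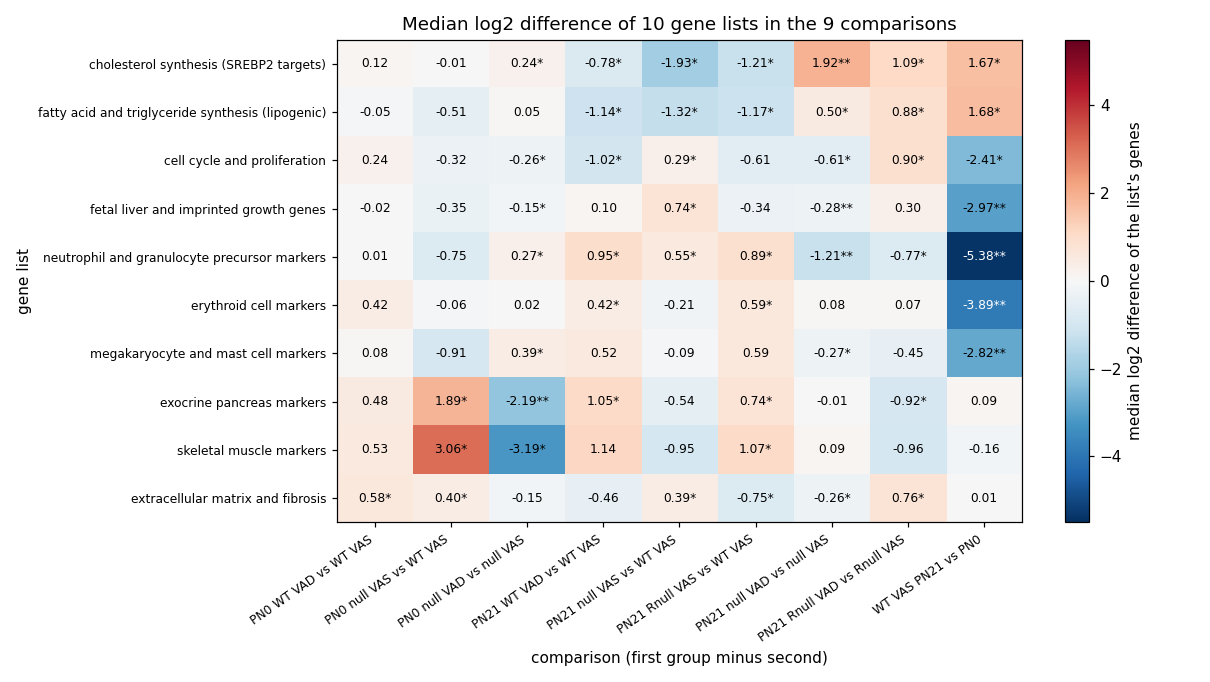
Median log2 difference (colour and number) of the genes of 10 lists (y axis) in the 9 comparisons (x axis, first group minus second). A single asterisk marks a list with a camera adjusted p under 0.05 with the preset correlation, and a double one a list that also passes with an estimated correlation; neutrophil markers range from -5.38 with age to 0.95 in deficient wild type.

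Between the diets of the R-Cyp1b1-null line at weaning, Cyp26a1 fell at least 6.12-fold (adjusted p = 0.042), from -0.10 in the sufficient group to a value on no deficient array well above background (-4.30 ± 0.65, SD, n = 3). It was lower on 3 of 3 slides, with differences from -5.80 to -2.30, and the fit with the slide as a block gave an adjusted p of 0.0374, but with the replicate number as a block it was not called (-4.19). In deficient against sufficient offspring of the other lines at weaning, Cyp26a1 was at least 3.32-fold lower in null and measured -1.11 ± 0.82 in wild type. The wild-type deficient and sufficient values were -3.02 and -1.65, -3.34 and -1.41, and -1.9 and -1.87 on slides 1 to 3. On slide 3 they hardly differed, and wild-type deficient array 2 was not well above background. The tests of the difference between lines called none of these Cyp26a1 effects different. Pnpla3 measured -1.27 ± 0.56 (-0.80 without sufficient array 2) and was lower on 3 of 3 slides (limma adjusted p = 0.342). Cyp26a1 was the 1 gene called, with 1882 at an unadjusted p under 0.05, and its call ended with quantile normalization (adjusted p = 0.349), where it differed by -4.45, with normexp background correction (-1.64), without the filter on dim probes or with groups of the same age alone in the fit (-4.19 in both), and on leaving out any of the 5 arrays other than sufficient array 3, where it differed by -4.51 to -3.72. Of the 19 lists called, such as fatty acid oxidation with a median of 1.46, 0 kept camera's call without the 2 arrays of low correlation, 10 turned, and 2 of these were called in the opposite direction. The fatty acid oxidation median was 4.37 on the slide of sufficient array 3 and 0.18 and -0.18 on the others, and the adjusted p was 0.667 with an estimated correlation.

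From birth to weaning in wild-type liver on the sufficient diet, 109 genes rose and 259 fell (n = 1 pool of 3 arrays against 2 litter pools). Many blood cell markers were lower at weaning. Neutrophil markers had a median of -5.38, and 14 of 24 fell, or 19 adjusted over the list alone, for example Stfa1 (-11.93 ± 1.10, well above background on 1 of the 3 PN21 arrays), Ltf (-7.92 ± 0.78) and Mpo (-7.47 ± 0.72). Erythroid markers had a median of -3.89, and 15 of 29 fell, or 22 adjusted over the list alone, with Ahsp, the chaperone of alpha globin, at -8.49 ± 0.87. Hemgn fell too, its brightest probe on no PN21 array well above background, and measured -5.60 with the mean of its probes. Of 14 megakaryocyte and mast cell markers 6 fell (median -2.82), Gp9 (-6.93), Ppbp (-7.31) and Pf4 (-5.66) among them. Of 22 fetal liver genes 7 fell, or 15 adjusted over the list alone, with a median of -2.97, and Igf2 (-10.57 ± 0.72), Afp (-9.22 ± 1.06) and Dlk1 (adjusted p = 6.41e-05, its brightest probe on no PN21 array well above background) led them. With an estimated correlation the adjusted p was 0.00584, 0.00175, 0.00584 and 7.65e-05 for these 4 lists. Cell cycle genes had a median of -2.41, and 1 of 36, the replication gene Mcm2, fell (-2.98 ± 0.73; adjusted p = 0.249 for the list with an estimated correlation).

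Among the genes that rose with age, the urinary protein genes Mup3 and Mup4 increased at least 698-fold and 142-fold. Hamp2, well above background on 1 of the 2 PN0 arrays, was called higher, and the lipogenic regulator Thrsp rose by 7.71 ± 1.76. Of 40 retinoid genes 2 rose, Rdh16 (4.47 ± 0.88) and Adh4 (4.19 ± 1.01), both dehydrogenases that act on retinol, or 7 adjusted over the list alone. The list had a median of 0.76 (camera adjusted p = 0.0132, and adjusted p = 0.74 with an estimated correlation). Tdo2 (6.41 ± 1.43, well above background on 1 of the 2 PN0 arrays) and Cyp4f14 (6.80 ± 1.22) rose among hepatocyte genes, and Saa2 (at least 87.3-fold) among acute phase genes. Across the alternative settings Tdo2 ranged from 4.29 to 8.53 and Saa2 from 4.65 to 8.34, and neither kept its call in all of them. Age went along with sex, as PN0 pools held litters and PN21 pools males, and with slide. With the slide as a random block 1112 genes were called, among them all 368. The median of all genes was 0.165, and -0.013 with quantile normalization, which shared 193 of its 369 calls. Leaving out PN0 array 2 gave 143 calls, PN0 array 1 221 calls and PN21 array 3 599 calls.

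Tests of the difference between effects were run for the pairs of comparisons that share a contrast. The diet effect on Ifi202b at weaning was larger in the null line than in wild type by 6.86 ± 0.87 (adjusted p = 0.0128) and than in the R-Cyp1b1-null line, where the difference was -6.43 ± 0.73 (adjusted p = 0.00329), and larger at weaning than at birth in the null line by 6.22 ± 0.80 (adjusted p = 0.0168). Ifi202b was not well above background in the sufficient null group, so these sizes are set against background, as are those of Kdm5d, on no PN0 null array well above it, and of Hamp, on no wild-type deficient PN21 array well above it. The genotype effect differed between weaning and birth for Igf2 by 6.51 ± 0.93 (adjusted p = 0.0288, and 5.72 and not called with the mean of its probes), which was higher in null liver at weaning. It also differed for Kdm5d by 5.10 ± 0.63 (adjusted p = 0.0092), which was lower in null liver at birth and measured -0.10 ± 0.49 at weaning. These calls ended with quantile normalization. Across the alternative settings the 3 Ifi202b differences ranged, in the order given, from 2.02 to 7.49, -6.7 to -1.28 and 1.26 to 6.45. The Igf2 difference ranged from 4.78 to 6.87 and that of Kdm5d from 0.86 to 5.33. The difference of Ifi202b between null and wild type was not called without wild-type deficient array 1 (6.73), null sufficient array 1 (6.70) or 2 (7.02), or null deficient array 1 (6.62), and that between R-Cyp1b1-null and null not without null sufficient array 1 (-6.27) or null deficient array 1 (-6.19). That between ages was not called without 7 of the 8 null arrays, null deficient PN21 array 2 being the exception (range 5.98 to 6.38). The differences of Igf2 and Kdm5d were not called without any single PN21 or PN0 null sufficient array (6.44 to 6.59 and 4.96 to 5.23) or without PN0 wild-type array 1 (6.25 and 4.91), nor that of Igf2 without array 2 (6.78). The Hamp diet effect differed between null and wild type by 13.02 ± 2.56 (limma adjusted p = 0.987). Neutrophil markers differed in diet effect between weaning and birth in the null line (median -1.58, camera adjusted p = 7.8e-33, and adjusted p = 0.0283 with an estimated correlation). Cholesterol synthesis genes differed in diet effect between the null line and wild type at weaning by a median of 2.66 (adjusted p = 2.4e-25, and adjusted p = 0.226 with an estimated correlation). Limma called 0 in the difference of diet effects between null and wild type at birth (317 at an unadjusted p under 0.05) and between R-Cyp1b1-null and wild type (1905).

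Set directly against each other on the sufficient diet, the R-Cyp1b1-null and null lines differed in 3407 genes, 3258 of them higher in R-Cyp1b1-null. Ifi202b (at least 29.3-fold) and Lvrn (at least 11.4-fold) were higher in that line, and Igf2 was lower (-5.55 ± 0.53). Across the alternative settings Ifi202b differed by 1.47 to 7.01, Lvrn by 0.37 to 5.5 and Igf2 by -6.38 to -4.58. The median of all genes was 0.05, and -0.389 with quantile normalization, which called 765 genes, 376 higher and 389 lower, 412 of them among the 3407. Without null sufficient array 1 or 2 the calls numbered 2081 and 1816. The lines lay on different slides, and with the slide as a random block 2945 genes were called. Probes of Xist and Uty that were not well above background measured -7.33 and -7.28, and -7.2 and -7.42, on the sufficient null arrays. On R-Cyp1b1-null sufficient arrays 1 and 2 they measured -5.89 and -5.35, and -3.71 and -3.99, also not well above background. Dim probes could thus come out higher in R-Cyp1b1-null through a lower signal floor on the null slide.

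Whether deficiency and deletion acted on the same genes was examined across genes, which are not independent replicates. Over 20452 genes the effect of deficiency in wild type and that of the null genotype at PN0 correlated at r = -0.17, where unchanged groups against the shared control gave 0.50, and their covariance was -0.15 against 0.31. Without the 2 arrays of low correlation, which belong to other groups, the covariance of unchanged groups was 0.11. The simulated noise held no differences between slides, though null and wild-type PN0 arrays lay on different ones. With 1 control array for each effect r was -0.26 either way, with covariances of -0.28 and -0.26. At PN21 the effects of the 2 null lines against the shared wild-type pool correlated at -0.40 (0.71 for unchanged groups), with a covariance of -0.47 against 0.62. This rested on the R-Cyp1b1-null array of low correlation: without the 2 such arrays r was 0.25 (0.67 for unchanged groups) and the covariance 0.16 against 0.22. Diet effects at PN21 correlated at -0.80 between wild type and R-Cyp1b1-null, which share no sample but each hold 1 array of low correlation on the same slide (-0.21 without these), and at 0.00 and 0.01 for the other pairs.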

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

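The tests of scaling, of the signal floor, of slides, of litter sex, of scan day, of blood-forming cells and of the shared control were chosen after the result was seen.

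The diet effect on Ifi202b at weaning differed between the null line and wild type (6.86, adjusted p = 0.0128), between the R-Cyp1b1-null and null lines (-6.43, adjusted p = 0.00329) and, within the null line, between weaning and birth (6.22, adjusted p = 0.0168). Each came out by a test of the difference itself in limma. Across the alternative settings they ranged from 2.02 to 7.49, from -6.7 to -1.28 and from 1.26 to 6.45, and not all were called. The signal was near the detection limit on both sufficient null arrays at PN21 and on all PN0 null arrays, and well above background on both deficient null arrays. Ifi202b expression is known to differ between inbred strains, and strain background of the pooled mice was not tested.

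The genotype effect differed between weaning and birth for Igf2 (6.51, adjusted p = 0.0288) and Kdm5d (5.10, adjusted p = 0.0092, its PN0 null values not above background), and 3407 genes were called between the R-Cyp1b1-null and null lines on the sufficient diet. These differences were tested directly in limma. Across the alternative settings that of Igf2 ranged from 4.78 to 6.87 and that of Kdm5d from 0.86 to 5.33. Of the 3407 genes, 3258 were higher in R-Cyp1b1-null. The median of all genes moved from 0.05 to -0.389 with quantile normalization. The lines lay on different slides, so line and slide cannot be told apart in that count.

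Kdm5d, Ddx3y and Eif2s3y were low and Xist was high on the PN0 null arrays. The mean of these 3 Y-linked genes was -7.30, -5.15, -7.19 and -7.54 on the 4 PN0 null arrays, with Ddx3y and Eif2s3y above background on 1 of them and Kdm5d on none. PN0 wild-type deficient array 1 in turn lacked Xist (-5.29). Scan day and grid version, shared with the PN21 null slide, are argued against: on that slide the same genes differed by 0.09 from the wild-type PN21 arrays other than deficient array 3, with a spread of 0.26, and by 0.28 from all 6, with a spread of 0.51. A litter pool with few or no males is a candidate explanation. That 0 of 24 arrays lacked both Xist and the Y-linked genes does not test it, as any pool of males or females would give this. The fall of these genes at PN0 and the Kdm5d difference between ages may thus follow the sex of the pooled pups. Sex stays open as a cause of other PN0 differences between genotypes and of those between the wild-type diets at PN0.

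Genes called lower outnumbered those called higher in null against wild-type liver at PN0, 347 against 154. With quantile normalization 13% of the calls were lower, but without the 2 arrays of low correlation, which belong to other groups, it gave 1409 higher and 1435 lower (50.5%), so scaling of the arrays stays open. Of the 347, 303 lay among the dimmest of 3 equal groups of genes. Probes of Ifi202b and Usp9y, for example, were well above background on no PN0 array. They measured -5.44 to -4.18 and -5.04 to -4.98 on the wild-type arrays. On the null arrays they measured -8.05 to -7.73 and -7.79 to -7.52, so the signal floor under these probes lay lower on the null slide. The dimmest group differed from the brightest by -0.25 in its median, a value between the bounds set. How many of the lower calls the floor accounts for thus stays open. The 3 arrays of the same wild-type PN21 pool differed by up to 1.69 in the same quantity, so slides could give a shift of this kind. No technical explanation tested is argued against, and the genotype stays open beside them.

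Igf2 and other genes that fell from birth to weaning lay higher in the PN21 null sufficient group. Of the 259 genes that fell, 162 lay higher than in wild type (median 0.16), and 207 lay lower in deficient than in sufficient null liver. More blood-forming cells of every kind in sufficient than in deficient null liver are argued against. Erythroid markers had a median of 0.08 between these diets (pairs of arrays from -0.17 to 0.27). An excess over wild type in both null groups would not show in this test and stays open. A less mature liver in the null sufficient group may account for the pattern: genes that rose with age had a median of 0.24 between the diets (0.21 to 0.29 over pairs of arrays), although against wild type they had medians of -0.36 in null and -0.41 in R-Cyp1b1-null liver alike. The slide of the null arrays cannot be told apart, with a median of -0.34 for genes that fell (pairs from -0.48 to -0.18). The shared wild-type control stays open too, since the same genes had a median of 0.14 in R-Cyp1b1-null against that control. The R-Cyp1b1-null medians of -0.41 and 0.14 take in sufficient array 3, of low correlation, and were not computed without it. Adult hepatocyte genes in that comparison had medians of 0.46, -0.03 and -3.88 on slides 1 to 3.

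The 1 gene called between the diets of the R-Cyp1b1-null line was set against the other splits of the 6 arrays. Of 10 splits, 1 gave as many calls, the real one, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split had 1882 genes in limma and the others 1160 to 4644, 6 of the 9 having more. So few splits allow no share under 0.05.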

How the results depend on the processing

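The fits without the 2 arrays of low correlation, with array weights and with the control array of the same scan day were chosen after seeing the data. Of 155 results for named genes none reversed among those called. Of the 76 called, 25 kept their call in every setting tried, and 51 lost it in at least 1, 36 of them with quantile normalization and 36 with normexp correction. Of 67 with an unadjusted p of 0.05 or more, 37 turned sign in at least 1 setting and 4 were called in at least 1. The cause was not tested except where stated. The series table of the authors gave 497 calls in null against wild type at PN0 and 367 with age.

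With normexp background correction and quantile normalization, limma called 14 genes in null against wild type at PN0, 1 in that comparison at PN21, 4 between R-Cyp1b1-null and null, and 0 between the diets of the null line at PN21 (50 at an unadjusted p under 0.05) and of the R-Cyp1b1-null line (1402). It also called 0 in the differences of diet effect between null and wild type at PN21 (86), between R-Cyp1b1-null and null (105) and between ages in the null line (33), and 0 in the genotype effect between ages (234). The Cyp1b1 difference at PN0 was 2.05, not called.

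With quantile normalization alone limma called 146 genes in null against wild type at PN0, 765 between R-Cyp1b1-null and null, and 0 in null against wild type at PN21 (950 at an unadjusted p under 0.05) and between the R-Cyp1b1-null diets (1980). It called 0 in the differences of diet effect between null and wild type at PN21 (108), R-Cyp1b1-null and null (182) and ages (29), and 0 in the genotype effect between ages (334). Of 297 list tests 90 were called, and 8 with the inter-gene correlation estimated in place of the preset one. The median of all genes moved by -0.145 and 0.15 in the R-Cyp1b1-null genotype and diet comparisons.

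With no filter on dim probes 2577 genes were called in null against wild type at PN0, 9296 between R-Cyp1b1-null and null, 0 between the R-Cyp1b1-null diets by limma (2278 at an unadjusted p under 0.05) and 1 in the genotype effect between ages. With the mean of probes that last count was 1.

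With the 3 arrays of the wild-type sufficient PN21 pool as replicates, 327 genes were called in null against wild type at PN0, 2021 at PN21, 4 between wild-type diets and 2 between null diets at PN21, and 1516 with age. With groups of the same age alone in the fit, the calls were 172 between wild-type diets and 5456 between genotypes at PN0, and 1 in the difference of diet effects there. That fit called 0 by limma in null against wild type at PN21 (2090 at an unadjusted p under 0.05), between the R-Cyp1b1-null diets (418) and in the differences of diet effect between null and wild type (65) and between R-Cyp1b1-null and null (80) at PN21.

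With the slide as a block 1 gene was called between wild-type diets and 3 between null diets at PN21, and 2 in the difference of diet effects between R-Cyp1b1-null and null. With the slide as a random block 1636 were called in null against wild type at PN21 and 1112 with age. Arrays of the same number, with group means removed, correlated at -0.59 to 0.4. Where both groups held 2 arrays, same and other numbers give the same value with opposite sign. Arrays of low correlation enter some of the larger groups. These values thus do not settle whether array numbers pair samples. With the replicate number as a block the calls were 1409 in null against wild type at PN0 and 1738 at PN21, 1 between wild-type diets at PN21, 2777 with age, 61 in the genotype effect between ages, and 0 by limma between the R-Cyp1b1-null diets (2744 at an unadjusted p under 0.05).

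Without the 2 arrays of low correlation 569 genes were called between wild-type diets and 6248 between genotypes at PN0, 2665 in null and 2 in R-Cyp1b1-null against wild type at PN21, 2 between null diets and 3424 with age. The differences gave 10 between null and wild type in diet effect at PN0, 1 between R-Cyp1b1-null and wild type, and 28 in the genotype effect between ages. With the slide block added, the diets gave 1093 calls in wild type at PN0, 12 in wild type and 6 in null at PN21, 2 genes were called in R-Cyp1b1-null against wild type, and the differences of diet effect gave 32 (PN0), 9 (null and wild type at PN21) and 2 (R-Cyp1b1-null and wild type). These fits hold fewer arrays.

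With array weights the diets gave 247 calls in wild type and 1 in null at PN0, and 6 in wild type and 130 in null at PN21. The genotypes gave 8322 at PN0, 3452 (null) and 2 (R-Cyp1b1-null) at PN21 and 7484 between R-Cyp1b1-null and null, and age gave 4173. The differences gave 12 in diet effect at PN0, 25, 1 and 2 at PN21 (null and wild type, R-Cyp1b1-null and wild type, R-Cyp1b1-null and null), 2 between ages and 169 in the genotype effect.

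With quantile normalization without the 2 arrays the diets gave 170 calls in wild type at PN0, 2 in wild type and 2 in R-Cyp1b1-null at PN21, the genotypes 2844 at PN0, 549 (null) and 1 (R-Cyp1b1-null) at PN21 and 1746 between R-Cyp1b1-null and null, and age 2489. The differences gave 7 in diet effect at PN0 and 10 in the genotype effect, and limma called 0 in diet effect between null and wild type (444 at an unadjusted p under 0.05), R-Cyp1b1-null and null (422) and ages (185). List tests called without the 2 arrays numbered 102.

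Within 40 Mb of Cyp1b1, 6 of 308 genes were called at PN0, an odds ratio of 1.04 (two-sided Fisher's exact test, p = 0.831) against 0 within 20 Mb, a wider window with more genes.

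Leaving out each array in turn, a lone remaining array assumed to vary like the other groups, gave ranges of limma calls. They were 0 to 0 between wild-type diets at PN0 and at PN21 and in R-Cyp1b1-null against wild type, 1 to 47 in null against wild type at PN0 and 0 to 1038 at PN21, 0 to 11 between null diets at PN0 and 1 to 2 at PN21, 0 to 1 between R-Cyp1b1-null diets, 143 to 599 with age, and 1816 to 4717 between R-Cyp1b1-null and null. The differences gave 0 to 2, except 0 to 0 between R-Cyp1b1-null and wild type. The Cyp1b1 difference at PN0 ranged from 4.89 to 5.67. Signal over background limited dim genes: 33.7% of probes were well above it on the array with the lowest share.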
